A study of Danio rerio with 9 samples.

How the data were processed

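Poly A RNA from livers microdissected from wild-type zebrafish larvae was sequenced in 9 libraries, 3 from larvae given vehicle, 3 from larvae given 1 mM metronidazole and 3 from larvae given 10 mM metronidazole, each for 24 h. Per the labels, the authors aligned the reads with HISAT2 and counted them per gene with featureCounts on genome build GRCz11. The versions, the annotation release, the strand setting and the treatment of reads that map to more than 1 place are not given in the sources used here. The deposited table holds raw counts per gene, not normalised, for 32520 Ensembl genes. In each library, 75.2 to 82.9% of the counts from 1 to 20 were even, against 48.7 to 51.0% of the counts above 1000, as when both mates of a read pair are counted, so that a deposited count is mostly a read and not a fragment. Total counts per library ranged from 30 to 41.3 M, and per-gene precision at this depth is given by the standard errors of the fits. By the column names, 10 mM replicate 3 was sequenced on lane 8 and the other libraries on lane 7.

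The samples were grouped by the treatment in their labels. The labels do not say whether replicates were separate animals, pools or clutches, so each p-value measures only the spread between these libraries, part of which may be technical. The replicate numbers were not used as pairs. Genes passed filterByExpr in edgeR (version 4.0.16, R 4.3.3) with a minimum count of 10 and a minimum total count of 15, which left 16766 genes, 16035 of them with a symbol. Libraries were scaled by TMM factors. One model with a mean per group was fitted to all 9 libraries, and each of the 3 pairs of groups was compared by the edgeR quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An F test over the 3 groups used the same fit. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of its F statistic. Levels are given as CPM, counts scaled to the same total, on TMM-scaled library sizes, as mean ± SD over 3 libraries. The median log2 fold change of all tested genes was -0.03, 0.01 and -0.04 in the 3 comparisons.

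Before the data were examined, the comparisons, 49 gene lists (33 of pathways and processes and 16 of cell type markers), the alternatives and the rule for the genes named were fixed. The rule took, per comparison and direction, the 8 genes with the largest log2 change among those past the threshold with a symbol, a mean of at least 1 CPM and no overlap between the 3 libraries of each group. It also took the 3 members of each list with the smallest p at 10 mM. Genes named outside the rule are said to have been chosen after their values were seen. Of 1719 list members, 1588 matched 1 gene each, and 46 of the lists had 80% or more of their members matched. Each list was tested with camera in limma (version 3.58.1) against all other tested genes, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the 49 lists, and again with a correlation estimated from the residuals. The limma test fry, which asks whether a list's members move on balance in 1 direction and not whether they differ from other genes, was a further alternative. Counts of passing members are given over all genes and adjusted over the list alone. The relation between the changes at both doses was compared with 100 simulations of unchanged groups that share the 3 vehicle libraries, with negative binomial counts at the fitted dispersions.

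The alternatives were DESeq2 (version 1.42.0) size factors in the edgeR test, the DESeq2 test itself, no count filter, a filter of at least 5 CPM in 3 libraries, only the 6 libraries of the groups compared, the replicate number as a block, leaving out the mitochondrial genes and the 20 most abundant genes, a log2 fold change of at least 1 in size, and leaving out each library in turn. Members of lists were also counted without 1 mM replicate 3 and without 10 mM replicate 3, and the counts were halved, both chosen after the data were seen. The pipeline was tested on simulated data with 200 changed genes, where it recovered 39 to 49% of genes changed 2-fold and 73 to 77% of genes changed 4-fold. False calls made up 6.11%, 2.56% and 12.1% of the simulated calls for 10 mM against vehicle, 1 mM against vehicle and 10 mM against 1 mM, so the first and the last of these lay above the nominal 5%. Reads shared between near-identical genes, as in the cyp2 and ugt families, could not be separated from these counts. Transcript isoforms and positions were not analysed here, and not every gene that the rule named is reported here.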

Results

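Gene expression was measured by RNA sequencing in livers of wild-type zebrafish larvae kept for 24 h in vehicle, 1 mM metronidazole or 10 mM metronidazole, with 3 libraries per group. Metronidazole is the nitroimidazole prodrug that bacterial nitroreductase turns into a toxin in transgenic cell ablation. The series concerns a system for partial ablation and lineage tracing, and these larvae were wild-type, so the comparisons measure the drug without the transgene. Total counts were 37.2, 38.3 and 39.3 M in the vehicle libraries, 34.1, 33.6 and 36 M at 1 mM, and 41.3, 38.6 and 30 M at 10 mM. On the second principal component, 17.4% of the variance, 1 mM replicate 3 stood at -76.8 and the other libraries between -6 and 26.6.

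At 10 mM against vehicle, which asks what the higher dose does to the liver, the complement gene c7b (ENSDARG00000057121) rose from 7.51 ± 2.74 to 326 ± 102 CPM (SD, n = 3 each), 43.4-fold (log2 5.44, SE 0.32, adjusted p = 2.31e-06). The cationic amino acid transporter slc7a3a (ENSDARG00000020645) rose from 8.48 ± 1.59 to 285 ± 116 CPM (log2 5.07, SE 0.45, adjusted p = 2.12e-05). The gene of the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, pck1 (ENSDARG00000013522), rose from 281 ± 116 to 6503 ± 1733 CPM (log2 4.53, SE 0.53, adjusted p = 0.000107). Glucokinase, gck (ENSDARG00000068006), the first enzyme of hepatic glucose use, fell from 6.33 ± 2.64 to 0.303 ± 0.128 CPM (log2 -4.34, SE 0.62, adjusted p = 0.000438). The G protein subunit gene gnai2b (ENSDARG00000017294) fell from 71.9 ± 8.37 to 9.20 ± 0.443 CPM (log2 -2.96, SE 0.13, adjusted p = 2.09e-07).

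The other genes with the largest rises at 10 mM were fosab (ENSDARG00000031683, log2 5.14, SE 0.84), an immediate early transcription factor gene, slc26a5 (ENSDARG00000022424, log2 4.82, SE 0.46), dio3b (ENSDARG00000095767, log2 4.65, SE 0.58), whose product inactivates thyroid hormone, btg2 (ENSDARG00000020298, log2 4.61, SE 0.68) and nek2 (ENSDARG00000005619, log2 4.60, SE 0.63). At 10 mM fosab (62.9 ± 51.3 CPM) and btg2 (75.7 ± 64.7 CPM) varied widely, and nek2 was low in vehicle (0.106 ± 0.0573 CPM). The other genes with the largest falls were rasl11b (ENSDARG00000015611, log2 -3.83, SE 0.40), cabp2b (ENSDARG00000052277, log2 -3.00, SE 0.45), the chemokine gene ccl39a.10 (ENSDARG00000096060, log2 -2.81, SE 0.49), the chemokine receptor gene cxcr4a (ENSDARG00000057633, log2 -2.75, SE 0.54), the fructose transporter gene slc2a5 (ENSDARG00000077875, log2 -2.61, SE 0.43) and the carotenoid oxygenase gene bco2l (ENSDARG00000027620, log2 -2.60, SE 0.19). The adjusted p of these other genes ranged from 8.28e-06 to 0.00351. None of these 16 genes overlapped between the groups, and each kept its call under every alternative that gave a value.

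**Figure D1:**
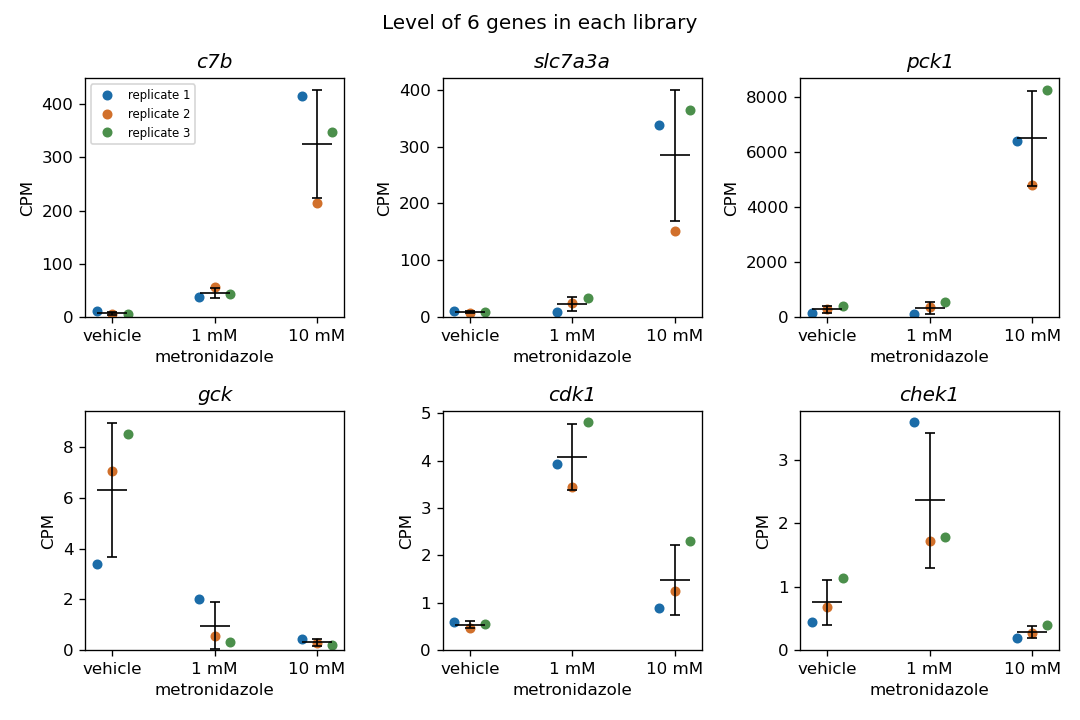
CPM (y axes, from 0) of c7b, slc7a3a, pck1, gck, cdk1 and chek1 in each library of the vehicle, 1 mM and 10 mM groups (x axes), with points for libraries and bars for mean ± SD of 3. The mean of c7b was 7.51, 45.5 and 326 CPM in the 3 groups, that of gck 6.33, 0.965 and 0.303 CPM, and that of cdk1 0.539, 4.07 and 1.48 CPM.

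Stress response genes rose at 10 mM. Of 24 tested genes of the Nrf2 oxidative stress response, 13 rose and 1 fell (14 and 2 adjusted over the list alone, median log2 change 0.58, camera adjusted p = 1.42e-14, and adjusted p = 0.212 with an estimated correlation). The glutathione synthesis gene gclm (ENSDARG00000018953) rose from 5.63 ± 0.719 to 51.1 ± 7.04 CPM (log2 3.18, SE 0.17, adjusted p = 8.12e-07) and the pentose phosphate gene pgd (ENSDARG00000015343) by 3.08 (SE 0.20) on the log2 scale. The member that fell was the heme oxygenase gene hmox1a (ENSDARG00000027529, log2 -1.26, SE 0.28, adjusted p = 0.00692), named after its values were seen. Of 34 unfolded protein response genes, 24 rose and 1 fell (25 and 1 adjusted over the list alone, median 0.68, adjusted p = 9.88e-13, and adjusted p = 0.233 with an estimated correlation), among the risen the endoplasmic reticulum chaperone gene hyou1 (ENSDARG00000013670, log2 1.79, SE 0.21). The 1 that fell was creb3l3a (ENSDARG00000056226, log2 -0.87, SE 0.26), named after its values were seen, with its call lost without any vehicle or 10 mM library or 1 mM replicate 2 (0.054 to 0.138). Of 30 genes of the amino acid and integrated stress response, 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.59, adjusted p = 1.66e-09, and adjusted p = 0.212 with an estimated correlation), led by slc7a3a, ddit4 (ENSDARG00000037618, log2 4.41, SE 0.49) and cebpb (ENSDARG00000042725, log2 1.27, SE 0.16). Of 26 heat shock response genes, 6 rose and 1 fell (12 and 2 adjusted over the list alone, median 0.44, adjusted p = 0.00267, and adjusted p = 0.234 with an estimated correlation). The 6 included hspa4a (ENSDARG00000004754, log2 3.23, SE 0.24) and the mitochondrial chaperone gene hspd1 (ENSDARG00000056160, log2 1.48, SE 0.14). The 1 that fell was fkbp4 (ENSDARG00000008447, log2 -0.67, SE 0.13), named after its values were seen. Without 1 mM replicate 3, 11 heat shock genes passed. The values with an estimated correlation, where these 4 calls were lost, were the highest of 14 alternatives, whose lowest were 5.24e-16, 3.34e-17, 4.68e-14 and 0.00043.

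Genes of ribosome assembly and of the proteasome rose with them. Of 55 ribosome biogenesis genes, 33 rose and 0 fell (39 and 0 adjusted over the list alone, median 0.55, adjusted p = 1.58e-12, and adjusted p = 0.233 with an estimated correlation), among them the nucleolar genes fbl (ENSDARG00000053912, log2 0.94, SE 0.13) and nop58 (ENSDARG00000104353, log2 0.95, SE 0.14). Of 36 proteasome genes, 16 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.50, adjusted p = 1.27e-07, and adjusted p = 0.56 with an estimated correlation). Without 10 mM replicate 3, 19 ribosome biogenesis genes and 10 proteasome genes passed, and without 1 mM replicate 3, 26 proteasome genes. Over 14 alternatives these p-values began at 3.03e-13 and 1.34e-09. The 76 cytosolic ribosomal protein genes themselves gave 0 passing members (0 adjusted over the list alone, median -0.13), and the list was not called (adjusted p = 0.246).

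Metabolic genes moved in both directions at 10 mM. Of 26 genes of gluconeogenesis and glycogen, 13 rose and 2 fell (15 and 5 adjusted over the list alone, median 0.50, adjusted p = 6.76e-05, and adjusted p = 0.234 with an estimated correlation), with pck1, the transcription factor gene foxo1a (ENSDARG00000099555, log2 1.85, SE 0.14) and the insulin-like growth factor binding protein gene igfbp1b (ENSDARG00000038666, log2 2.51, SE 0.26) higher. The 2 lower members, named after their values were seen, were the glycogen-targeting gene ppp1r3ca (ENSDARG00000071005, log2 -1.01, SE 0.18) and CREBRF (ENSDARG00000105114, log2 -0.72, SE 0.20). CREBRF missed the threshold without any vehicle or 10 mM library (adjusted p 0.063 to 0.0966). Of 22 glucocorticoid response genes, 12 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.82, adjusted p = 5.15e-07, and adjusted p = 0.234 with an estimated correlation), with sgk1 (ENSDARG00000025522, log2 2.35, SE 0.27) and igfbp1a (ENSDARG00000099351, log2 1.90, SE 0.23) higher. The glucocorticoid receptor gene nr3c1 (ENSDARG00000025032, log2 -0.65, SE 0.13) and the clock gene per1a (ENSDARG00000056885, log2 -0.91, SE 0.14), named after their values were seen, were lower. The lists share pck1 and igfbp1a. Of 24 genes of fatty acid and triglyceride synthesis, 8 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.38, adjusted p = 0.0174, and adjusted p = 0.482 with an estimated correlation), with elovl5 (ENSDARG00000004979, log2 1.05, SE 0.15) higher. Among the 8 was ENSDARG00000087657 (log2 1.08, SE 0.16), named fasn in a table of Ensembl names and ccdc57 in the deposited table. The carbohydrate-responsive transcription factor gene mlxipl (ENSDARG00000104054, log2 -1.50, SE 0.30) and acss2 (ENSDARG00000037781, log2 -0.76, SE 0.16), named after their values were seen, were lower. Over 14 alternatives the adjusted p of these 3 lists began at 3.37e-06, 1.36e-11 and 0.00604. The fatty acid synthesis call was lost without vehicle replicate 3 (adjusted p = 0.0717). Of 70 genes of the nuclear encoded respiratory chain, 7 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.14), and the list's adjusted p of 0.0355 became 0.0636 without vehicle replicate 3, 0.0944 without 10 mM replicate 1 and 0.133 without 10 mM replicate 2. It was lost, too, with adjusted p = 0.96 with an estimated correlation and reached 0.00248 at the lowest of 14 alternatives. Without 1 mM replicate 3, 16 of its genes passed.

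Genes of drug metabolism moved in both directions at 10 mM. Of 45 phase I genes, 16 fell and 4 rose (19 and 7 adjusted over the list alone, median -0.31, camera adjusted p = 0.00209, and adjusted p = 0.234 with an estimated correlation). Among those that fell were cyp2aa1 (ENSDARG00000099003, 61.3 ± 4.61 to 23.6 ± 2.65 CPM, log2 -1.38, SE 0.13), cyp2ad2 (ENSDARG00000021172, 1688 ± 72.7 to 666 ± 131 CPM, log2 -1.34, SE 0.16) and the xanthine dehydrogenase gene XDH (ENSDARG00000055240, log2 -1.08, SE 0.15). The 4 that rose were cyp1c1 (ENSDARG00000101195, log2 0.58, SE 0.17) and, named after their values were seen, cyp1c2 (ENSDARG00000101789, log2 0.82, SE 0.26), cyp2k6 (ENSDARG00000098995, log2 2.44, SE 0.76) and cyp2k8 (ENSDARG00000101190, log2 0.70, SE 0.21). All 4 missed the threshold without any vehicle library or 10 mM replicate 1 or 2 (adjusted p 0.0686 to 0.186). So did all but cyp1c1 without 1 mM replicate 2 (0.0507 to 0.0697). So did cyp1c2 and cyp2k6 without 10 mM replicate 3 or a count filter (0.0508 to 0.0625). cyp2k6 lay near the floor (0.0878 CPM in vehicle). Of 48 genes of phase II conjugation and export, 13 rose and 2 fell (16 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.00267, and adjusted p = 0.368 with an estimated correlation), among them ugt2b5 (ENSDARG00000116986, log2 1.31, SE 0.12) and sult3st2 (ENSDARG00000093619, log2 1.64, SE 0.16). The members that fell were sult1st6 (ENSDARG00000006811, log2 -0.73, SE 0.13) and ugt2a5 (ENSDARG00000011537, log2 -0.65, SE 0.20), the latter named after its values were seen. ugt2a5 missed the threshold without any vehicle library, 1 mM replicate 2 or 10 mM replicate 2 or 3 (adjusted p 0.0569 to 0.164). Of 6 tested genes of the aryl hydrocarbon receptor battery, 5 rose and 0 fell (5 and 1 adjusted over the list alone, median 0.70, adjusted p = 0.0108, and adjusted p = 0.234 with an estimated correlation). Of the 5, tiparp (ENSDARG00000061841, log2 1.59, SE 0.16) kept its call under every alternative, and the others were cyp1c1, cyp1c2, cyp2k6 and nqo1 (ENSDARG00000010250, log2 0.51, SE 0.14), which missed it without any vehicle library or 10 mM replicate 1 or 2 (adjusted p 0.0542 to 0.102 for nqo1). Of 19 genes of bile acid synthesis and transport, 7 fell and 1 rose (8 and 2 adjusted over the list alone, median -0.29, adjusted p = 0.00693, and adjusted p = 0.234 with an estimated correlation), with hsd3b7 (ENSDARG00000036966, log2 -1.44, SE 0.13) and the bile acid sensor target nr0b2a (ENSDARG00000044685, log2 -1.69, SE 0.27) lower and the transporter gene slco2b1 (ENSDARG00000054609, log2 0.89, SE 0.13) higher. Only 65.6% of the bile acid list matched a gene. These were the highest of 14 alternatives for the 4 lists, whose lowest were 0.00145, 0.000389, 0.00132 and 0.00132. Without 10 mM replicate 3, 12 phase I genes and 3 genes of the receptor battery passed.

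Lists not called at 10 mM included those of hepatocyte products. Of 30 hepatocyte secreted protein genes, 1 rose, agt (ENSDARG00000016412, log2 0.98, SE 0.18), and 1 fell, gc (ENSDARG00000089310, log2 -0.48, SE 0.13) (1 and 0 adjusted over the list alone, adjusted p = 0.985). Their median was -0.00, with a mean of 0.01. Of 32 complement and coagulation genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.985), with c7b, c6 (ENSDARG00000057113, log2 1.08, SE 0.13), f9b (ENSDARG00000029493, log2 0.71, SE 0.13) and f5 (ENSDARG00000055705, log2 0.61, SE 0.15) higher. The median of this list was -0.19, below 0, while its mean was 0.06 and its test pointed up. Of 31 p53 and DNA damage genes, 6 rose and 5 fell (8 and 5 adjusted over the list alone, median 0.16, adjusted p = 0.744), with tp53inp1 (ENSDARG00000028017, log2 1.84, SE 0.22) higher. The 5 lower were sesn3 (ENSDARG00000015822, log2 -1.27, SE 0.13), sesn1 (ENSDARG00000020693, log2 -1.45, SE 0.18), ddb2 (ENSDARG00000041140, log2 -1.14, SE 0.12), plk2b (ENSDARG00000019130, log2 -1.01, SE 0.18) and ccng2 (ENSDARG00000017602, log2 -0.76, SE 0.15). Of 39 acute phase and inflammation genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.27, adjusted p = 0.154). Higher were the AP-1 genes fosl1a (ENSDARG00000015355, log2 3.83, SE 0.34), junbb (ENSDARG00000104773, log2 3.79, SE 0.61) and junba (ENSDARG00000074378, log2 3.36, SE 0.37), with cebpb and relb (ENSDARG00000086173, log2 0.57, SE 0.17). Lower were the antimicrobial peptide gene leap2 (ENSDARG00000104654, log2 -2.08, SE 0.23), cxcl18b (ENSDARG00000075045, log2 -1.02, SE 0.19) and nfkb2 (ENSDARG00000038687, log2 -0.72, SE 0.15). Of 25 interferon response genes, 1 rose and 5 fell (2 and 6 adjusted over the list alone, median -0.45, adjusted p = 0.0975). The 1 higher was irf7 (ENSDARG00000045661, log2 1.29, SE 0.22), and lower were TAP1 (ENSDARG00000079766, log2 -1.10, SE 0.23), irf1b (ENSDARG00000043249, log2 -0.86, SE 0.22), irf9 (ENSDARG00000016457, log2 -0.77, SE 0.14), stat1a (ENSDARG00000006266, log2 -0.68, SE 0.15) and stat2 (ENSDARG00000031647, log2 -0.60, SE 0.11). Of 39 circadian clock genes, 5 rose and 11 fell (5 and 14 adjusted over the list alone, median -0.24, adjusted p = 0.0723). The 5 higher were rorcb (ENSDARG00000017780, log2 1.75, SE 0.16), npas2 (ENSDARG00000016536, log2 2.16, SE 0.40), nfil3-5 (ENSDARG00000094965, log2 1.25, SE 0.31), nr1d2a (ENSDARG00000003820, log2 1.06, SE 0.25) and lonrf1l (ENSDARG00000078567, log2 0.67, SE 0.13), and among the lower were bhlhe41 (ENSDARG00000041691, log2 -1.59, SE 0.15) and tefa (ENSDARG00000039117, log2 -1.05, SE 0.14). Of these genes f5, sesn1, plk2b, ccng2, junbb, relb, cxcl18b, nfkb2, TAP1, irf1b, stat1a, npas2, nfil3-5, nr1d2a and lonrf1l were chosen after their values were seen. gc missed the threshold without any vehicle or 10 mM library (adjusted p 0.0689 to 0.11). f5 missed it without vehicle replicate 2 or 3 or 10 mM replicate 1 or 3 (0.0607 to 0.0763). relb missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0864 to 0.14). irf1b missed it without vehicle replicate 2 or 3 or 10 mM replicate 1 (0.0757 to 0.081). nr1d2a missed it without vehicle replicate 2 or 10 mM replicate 3 (0.0545 to 0.0594). nfil3-5 missed it without vehicle replicate 1 or 2 (0.067 to 0.0679). With no count filter gc missed it too (0.0563).

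Among the other metabolic lists not called at 10 mM, cholesterol synthesis had 7 higher and 3 lower of 28 (8 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.0666). Higher were acat2 (ENSDARG00000007127, log2 2.49, SE 0.20), hmgcs1 (ENSDARG00000103025, log2 1.39, SE 0.17) and insig1 (ENSDARG00000010658, log2 2.04, SE 0.29), and lower tm7sf2 (ENSDARG00000032816, log2 -1.21, SE 0.17), fdft1 (ENSDARG00000101062, log2 -0.79, SE 0.23) and dhcr7 (ENSDARG00000103226, log2 -0.52, SE 0.14). Fatty acid oxidation had 7 higher and 3 lower of 38 (9 and 5 adjusted over the list alone, median 0.08, adjusted p = 0.246). The coactivator gene PPARGC1A (ENSDARG00000067829, log2 3.40, SE 0.34) and the carnitine transferase genes cpt1b (ENSDARG00000058285, log2 1.61, SE 0.28) and cpt1ab (ENSDARG00000062054, log2 0.83, SE 0.16) were higher, and eci1 (ENSDARG00000018002, log2 -0.64, SE 0.16), bdh1 (ENSDARG00000059388, log2 -0.55, SE 0.13) and acox3 (ENSDARG00000038865, log2 -0.48, SE 0.15) lower. Lipid transport had 7 higher and 2 lower of 26 (7 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.154), with apoa4a (ENSDARG00000101160, log2 2.34, SE 0.24) higher and apobb.2 (ENSDARG00000075016, log2 -1.13, SE 0.19) and abcg8 (ENSDARG00000063059, log2 -0.60, SE 0.12) lower. Glycolysis had 3 higher and 2 lower of 27 (3 and 3 adjusted over the list alone, median 0.00, mean -0.07, adjusted p = 0.985), with pfkfb4b (ENSDARG00000029075, log2 1.53, SE 0.23), aldoaa (ENSDARG00000011665, log2 0.57, SE 0.14) and gpia (ENSDARG00000012987, log2 0.44, SE 0.14) higher and gck and the phosphofructokinase gene pfklb (ENSDARG00000099755, log2 -1.36, SE 0.18) lower. The median of this list was above 0 and its test pointed down. Amino acid catabolism and the urea cycle had 10 higher and 5 lower of 43 (12 and 7 adjusted over the list alone, median 0.14, adjusted p = 0.246), with prodha (ENSDARG00000086746, log2 1.54, SE 0.19) higher and bckdk (ENSDARG00000016904, log2 -1.32, SE 0.15), glud1a (ENSDARG00000008816, log2 -0.48, SE 0.14), sardh (ENSDARG00000058102, log2 -0.47, SE 0.13), kmo (ENSDARG00000009160, log2 -0.44, SE 0.12) and haao (ENSDARG00000076487, log2 -0.43, SE 0.12) lower. Alcohol and aldehyde metabolism had 1 higher, akr1b1.1 (ENSDARG00000006215, log2 0.70, SE 0.16), and 4 lower of 20 (1 and 5 adjusted over the list alone, median -0.30, adjusted p = 0.0723), the latter akr1a1a (ENSDARG00000035257, log2 -0.77, SE 0.18), aldh3a2a (ENSDARG00000028259, log2 -0.60, SE 0.13), aldh1l1 (ENSDARG00000077004, log2 -0.55, SE 0.15) and aldh2.1 (ENSDARG00000089924, log2 -0.53, SE 0.16). Of these genes tm7sf2, fdft1, dhcr7, eci1, bdh1, acox3, abcg8, aldoaa, gpia, glud1a, sardh, kmo, haao, aldh1l1 and aldh2.1 were chosen after their values were seen. fdft1 missed the threshold without vehicle replicate 2 or 3 or 10 mM replicate 2 or 3 (adjusted p 0.0605 to 0.136). dhcr7 missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0586 to 0.106). eci1 missed it without vehicle replicate 1 or 2 or 10 mM replicate 3 (0.0694 to 0.0752). bdh1 missed it without vehicle replicate 2 or 10 mM replicate 2 (0.0513 to 0.0626). acox3 missed it without any vehicle library, 1 mM replicate 2 or 10 mM replicate 1 or 3 (0.0534 to 0.134). aldoaa missed it without vehicle replicate 2 or 10 mM replicate 1 or 3 (0.0523 to 0.0717). gpia missed it without any vehicle or 10 mM library or 1 mM replicate 2 (0.0693 to 0.177). glud1a missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0815 to 0.14). sardh missed it without any vehicle library or 10 mM replicate 1 or 3 (0.062 to 0.109). kmo missed it without vehicle replicate 1 or 2 or 10 mM replicate 1 or 3 (0.0722 to 0.0876). haao missed it without any vehicle or 10 mM library (0.0566 to 0.126). aldh1l1 missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0606 to 0.0953). aldh2.1 missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0744 to 0.136). With no count filter gpia, kmo and haao missed it too (0.0586, 0.052 and 0.056), and gpia without the mitochondrial and most abundant genes (0.0503).

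Hypoxia response had 4 higher and 3 lower of 23 at 10 mM (8 and 3 adjusted over the list alone, median 0.34, adjusted p = 0.103). Higher were hif1al (ENSDARG00000100826, log2 3.06, SE 0.29), igfbp1a, pfkfb4b and hif1al2 (ENSDARG00000044550, log2 0.98, SE 0.21), and lower ndrg1a (ENSDARG00000032849, log2 -1.64, SE 0.19), bnip3 (ENSDARG00000099961, log2 -0.86, SE 0.13) and erap1b (ENSDARG00000021859, log2 -0.85, SE 0.25). Iron and metal handling had 3 higher and 2 lower of 21 (3 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.246), with ncoa4 (ENSDARG00000021439, log2 1.65, SE 0.17), the transferrin receptor gene tfr1b (ENSDARG00000077372, log2 1.52, SE 0.22) and slc30a1a (ENSDARG00000005463, log2 0.96, SE 0.13) higher and hmox1a and slc39a10 (ENSDARG00000005823, log2 -1.44, SE 0.27) lower. The oestrogen response list had 3 higher and 0 lower of 11 (4 and 2 adjusted over the list alone, median 0.84, adjusted p = 0.16), the vitellogenin genes vtg7 (ENSDARG00000092419, log2 3.58, SE 0.62) and vtg5 (ENSDARG00000092126, log2 1.3, SE 0.38) and ctsl.1 (ENSDARG00000003902, log2 1.98, SE 0.60). Apoptosis and autophagy had 4 higher and 0 lower of 31 (4 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.382), with ulk1a (ENSDARG00000062518, log2 1.51, SE 0.23), mcl1b (ENSDARG00000008363, log2 1.33, SE 0.26), baxa (ENSDARG00000020623, log2 0.86, SE 0.21) and bcl2l1 (ENSDARG00000008434, log2 0.57, SE 0.17). The 13 mitochondrially encoded transcripts gave 0 passing members (0 adjusted over the list alone, median -0.10, adjusted p = 0.459). The cell cycle list had 1 higher, cdk1 (ENSDARG00000087554, log2 1.43, SE 0.36), and 0 lower of 58 (0 and 0 adjusted over the list alone, median 0.17, adjusted p = 0.683). Of these genes hif1al2, bnip3, erap1b, slc39a10 and bcl2l1 were chosen after their values were seen. erap1b missed the threshold without any vehicle library or 10 mM replicate 1 or 2 (adjusted p 0.0612 to 0.132). vtg5 missed it without vehicle replicate 2 or 3 or 10 mM replicate 1 or 3 (0.0618 to 0.171). ctsl.1 missed it without vehicle replicate 2 or 3, 1 mM replicate 2 or 10 mM replicate 1 or 3 (0.0525 to 0.141). baxa missed it without vehicle replicate 3 or 10 mM replicate 1 (0.0562 to 0.0582). bcl2l1 missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0828 to 0.179). cdk1 missed it without vehicle replicate 2 or 3 or 10 mM replicate 3 (0.0556 to 0.0746).

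Markers of other cell types gave 0 lists called by camera at 10 mM of 16, and 0 with an estimated correlation. Kidney tubule was the 1 list with an unadjusted camera p under 0.05 (0.0369) and the 1 called higher by fry (adjusted p = 0.011). Stellate cell and fibroblast markers had 4 higher and 2 lower of 25 (4 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.715), cxcl12a (ENSDARG00000037116, log2 1.00, SE 0.24), cxcl12b (ENSDARG00000055100, log2 0.96, SE 0.30), pdgfrb (ENSDARG00000100897, log2 0.70, SE 0.22) and sparc (ENSDARG00000019353, log2 0.47, SE 0.14) against desmb (ENSDARG00000005221, log2 -3.01, SE 0.75) and the collagen gene col1a1b (ENSDARG00000035809, log2 -0.60, SE 0.13). Macrophage markers had 4 higher and 2 lower of 23 (4 and 2 adjusted over the list alone, median 0.23, adjusted p = 0.259), marco (ENSDARG00000059294, log2 0.74, SE 0.13), spi1a (ENSDARG00000067797, log2 0.96, SE 0.21), ctss2.2 (ENSDARG00000013771, log2 1.2, SE 0.22) and grna (ENSDARG00000004954, log2 0.47, SE 0.15) against cd68 (ENSDARG00000055504, log2 -0.57, SE 0.13) and ptpn6 (ENSDARG00000089043, log2 -0.91, SE 0.21). Endothelial markers had 0 higher and 3 lower of 24 (0 and 3 adjusted over the list alone, median -0.03, adjusted p = 0.481), dll4 (ENSDARG00000070425, log2 -0.83, SE 0.14), erg (ENSDARG00000077304, log2 -0.77, SE 0.21) and cldn5b (ENSDARG00000014059, log2 -0.72, SE 0.18). Neutrophil markers had 3 higher and 0 lower of 17 (3 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.246), pnp5a (ENSDARG00000078619, log2 1.47, SE 0.19), lect2.1 (ENSDARG00000033227, log2 1.4, SE 0.33) and abcb9 (ENSDARG00000056200, log2 1.3, SE 0.25). Kidney tubule markers had 3 higher and 0 lower of 10 (3 and 0 adjusted over the list alone, median 0.08, adjusted p = 0.0975), slc22a6l (ENSDARG00000055523, log2 3.17, SE 0.69), slc20a2 (ENSDARG00000060796, log2 1.11, SE 0.14) and slc20a1a (ENSDARG00000020114, log2 0.55, SE 0.16). Of these genes pdgfrb, sparc, cxcl12b, spi1a, grna, cd68 and ptpn6 were chosen after their values were seen. cxcl12a missed the threshold without vehicle replicate 1 or 10 mM replicate 3 (adjusted p 0.0569 to 0.0606). cxcl12b missed it without vehicle replicate 1 or 2 or 10 mM replicate 1 or 2 (0.0642 to 0.187). pdgfrb missed it without any vehicle or 10 mM library or 1 mM replicate 2 (0.0517 to 0.166). sparc missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0663 to 0.113). desmb missed it without vehicle replicate 1 or 2 or 10 mM replicate 1 or 3 (0.0504 to 0.0716). grna missed it without any vehicle library, 1 mM replicate 1 or 2 or any 10 mM library (0.0506 to 0.197). ptpn6 missed it without vehicle replicate 3 (0.0527). erg missed it without vehicle replicate 1 or 3 or 10 mM replicate 1 or 3 (0.077 to 0.0959). cldn5b missed it without vehicle replicate 2 or 3 or 10 mM replicate 1 or 2 (0.054 to 0.0761). lect2.1 missed it without vehicle replicate 2 or 3 or 10 mM replicate 1 (0.0504 to 0.0609). slc20a1a missed it without any vehicle or 10 mM library (0.0532 to 0.121). So did grna with no count filter (0.0725) and pdgfrb with at least 5 CPM in 3 libraries (0.0555).

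Neural and eye markers had 2 higher and 0 lower of 9 at 10 mM (2 and 0 adjusted over the list alone, adjusted p = 0.812), atp1b2a (ENSDARG00000099203, log2 2.24, SE 0.32) and snap25b (ENSDARG00000058117, log2 1.56, SE 0.39), with a median of -0.21, a mean of -0.07 and a test that pointed up. Intestine markers had 1 higher and 2 lower of 20 (1 and 2 adjusted over the list alone, adjusted p = 0.985), mttp (ENSDARG00000008637, log2 0.52, SE 0.12) against pllp (ENSDARG00000062756, log2 -1.06, SE 0.22) and sult1st6, with a median of -0.04, a mean of 0.23 and a test that pointed down. Epidermis markers had 1 higher and 1 lower of 22 (1 and 1 adjusted over the list alone, median -0.10, adjusted p = 0.698), cldn1 (ENSDARG00000040045, log2 1.27, SE 0.17) and krt5 (ENSDARG00000058371, log2 -4.75, SE 1.29). Muscle markers had 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone, median -0.03, adjusted p = 0.842), acta1a (ENSDARG00000036371, log2 2.30, SE 0.42) and tpm2 (ENSDARG00000104682, log2 -0.51, SE 0.12). Lymphocyte markers had 1 higher of 10, dusp2 (ENSDARG00000098108, log2 3.07, SE 0.49) (1 adjusted over the list alone, median -0.42, adjusted p = 0.812). Erythroid markers had 2 lower of 26, creg1 (ENSDARG00000105154, log2 -0.59, SE 0.17) and nprl3 (ENSDARG00000010918, log2 -0.51, SE 0.13) (2 adjusted over the list alone, median -0.09, adjusted p = 0.715). Endocrine pancreas markers had 1 higher of 12, arxa (ENSDARG00000058011), which lay near the floor (0 adjusted over the list alone, median -0.19, adjusted p = 0.985). Biliary, thrombocyte, exocrine pancreas, and cartilage and notochord markers gave 0 passing members of 18, 12, 30 and 9 (0 adjusted over the list alone in each). Their medians were 0.03, -0.07, 0.07 and -0.13 and their adjusted p 0.945, 0.819, 0.985 and 0.744, and the biliary test pointed down against its median. snap25b missed the threshold without vehicle replicate 2 or 3 or 10 mM replicate 1 (adjusted p 0.0655 to 0.069). krt5 missed it without vehicle replicate 3 or 10 mM replicate 2 or 3 (0.0774 to 0.136). tpm2 missed it without vehicle replicate 3 or 10 mM replicate 1 or 3 (0.0526 to 0.0661). creg1 missed it without any vehicle library or 10 mM replicate 1 or 3 (0.0521 to 0.113). nprl3 missed it without vehicle replicate 1 or 3 or 10 mM replicate 1 or 3 (0.0515 to 0.0824). arxa missed it without vehicle replicate 2 or 3, 1 mM replicate 2 or 10 mM replicate 1 or 2 (0.0529 to 0.117).

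In all, 1633 genes were higher and 1245 lower at 10 mM than in vehicle by the edgeR quasi-likelihood test, out of 16766, and 742 and 477 of them changed at least 2-fold. The 3 libraries of each group did not overlap in 40.6% of genes, where chance gives 10%. The number higher was 1084 without vehicle replicate 3. The number lower was 809, 780 and 770 without vehicle replicates 1, 2 and 3, 776 without 10 mM replicate 1, and 805 without 10 mM replicate 3. Lane 8 held only that last library, so no value within that lane exists. On lane 7 alone, 1183 genes were higher and 805 lower. Of 49 lists camera called 14, 0 with an estimated correlation, and fry 19, of which 13 were the same.

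At 1 mM against vehicle, which asks what the lower dose does, genes of cell division rose together. Of 58 cell cycle genes, 26 rose and 0 fell (51 and 0 adjusted over the list alone), with a median log2 change of 1.47, and the list was called in camera (adjusted p = 1.39e-71, and adjusted p = 0.0353 with an estimated correlation, the highest of 14 alternatives that began at 9.14e-76). The mitotic kinase gene cdk1 rose from 0.539 ± 0.0674 to 4.07 ± 0.695 CPM (SD, n = 3 each, log2 2.91, SE 0.36, adjusted p = 0.0028), and the ribonucleotide reductase gene rrm2 (ENSDARG00000078069), 1 of a pair of genes with that symbol, from 2.34 ± 0.602 to 13.1 ± 2.44 CPM (log2 2.48, SE 0.28, adjusted p = 0.00201). The condensin gene ncapg (ENSDARG00000070109) rose by 1.87 on the log2 scale (SE 0.23, adjusted p = 0.00273) and the replication clamp gene pcna (ENSDARG00000054155), named after its values were seen, by 1.48 (SE 0.20, adjusted p = 0.00506). It was the only list, of 39 calls over the 3 comparisons, whose call held with an estimated correlation. Without 1 mM replicate 3, 20 of the 58 passed.

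Outside this list, c7b rose at 1 mM from 7.51 ± 2.74 to 45.5 ± 9.33 CPM (log2 2.60, SE 0.28, adjusted p = 0.0019), and the histone gene hist2h2l (ENSDARG00000068996) fell from 19.9 ± 2.55 to 9.34 ± 0.118 CPM (log2 -1.09, SE 0.14, adjusted p = 0.0028). Other genes with the largest rises were the DNA glycosylase gene neil3 (ENSDARG00000020079, log2 2.63, SE 0.54), the kinetochore gene mis12 (ENSDARG00000026454, log2 2.60, SE 0.51), the muscle actin gene acta1a (log2 2.54, SE 0.42), ercc6l (ENSDARG00000002479, log2 2.51, SE 0.46) and the DNA repair gene fanci (ENSDARG00000026224, log2 2.48, SE 0.38). Other genes with the largest falls were gck (log2 -2.69, SE 0.54), OTOP1 (ENSDARG00000021566, log2 -1.14, SE 0.24), bhlhe41 (log2 -0.88, SE 0.15), ptpn11b (ENSDARG00000012340, log2 -0.86, SE 0.14), selenoo1 (ENSDARG00000041951, log2 -0.79, SE 0.13), mtus1b (ENSDARG00000034105, log2 -0.78, SE 0.13) and the ornithine aminotransferase gene oat (ENSDARG00000078425, log2 -0.78, SE 0.16). The adjusted p of these 12 ranged from 0.0122 for fanci to 0.044 for OTOP1, and by the rule that picked them none overlapped between the groups. All 12 missed the threshold without vehicle replicate 1 (adjusted p 0.07 to 0.147) and without vehicle replicate 2 (0.0713 to 0.214). Without vehicle replicate 3, gck, OTOP1, oat, neil3, ercc6l, bhlhe41, selenoo1 and mtus1b missed it (0.0571 to 0.165), and without 1 mM replicate 2 so did all but ercc6l and fanci (0.0557 to 0.137). Without 1 mM replicate 3, OTOP1, neil3 and mis12 missed it (0.0512 to 0.0853), and without 1 mM replicate 1, neil3 (0.0624). The same held for gck, oat and neil3 without 10 mM replicate 1 (0.0525, 0.071 and 0.0621), gck and oat without 10 mM replicate 2 (0.0605 and 0.0557), and gck, OTOP1 and oat without 10 mM replicate 3 (0.0501, 0.0635 and 0.0515). With only the 2 groups compared, gck, oat, OTOP1, neil3 and mis12 missed it (0.0826, 0.0826, 0.064, 0.0534 and 0.0662), and with at least 5 CPM in 3 libraries OTOP1 and oat (0.0664 and 0.0604).

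Of 34 unfolded protein response genes, 6 rose and 0 fell at 1 mM (13 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 7.5e-10, and adjusted p = 0.443 with an estimated correlation, the highest of 14 alternatives that began at 4.71e-13). Among the 6 were hyou1 (log2 1.11, SE 0.20), the chaperone genes hspa5 (ENSDARG00000103846, log2 1.43, SE 0.25) and calr (ENSDARG00000076290, log2 0.89, SE 0.14), the last pair named after their values were seen. Each of these missed the threshold without any vehicle library or 1 mM replicate 2 (adjusted p 0.0623 to 0.156). The circadian clock list was called lower (median -0.12, adjusted p = 0.0206), with rorcb higher (log2 1.35, SE 0.16, adjusted p = 0.0026), bhlhe41 lower and the other members not passing (2 higher and 9 lower adjusted over the list alone). This call was lost without vehicle replicate 3 (0.106) and 1 mM replicate 3 (0.226), and with adjusted p = 0.775 with an estimated correlation, against 0.00228 at the lowest of 14 alternatives. The vitamin D hydroxylase gene cyp24a1 (ENSDARG00000103277), named after its values were seen, rose from 246 ± 61.1 to 759 ± 235 CPM (log2 1.63, SE 0.24, adjusted p = 0.0116), and its call was lost without vehicle replicate 2 (0.0752).

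At 1 mM the passing members of lists not called were c7b (complement), gck (glycolysis), oat (urea cycle), acta1a (muscle) and dgat1a (ENSDARG00000103503, log2 1.1, SE 0.22) of fatty acid synthesis, chosen after its values were seen. The call of the last was lost without any vehicle library, 1 mM replicate 2 or 3 or any 10 mM library (0.0502 to 0.165). The other lists called at 1 mM rested on 1 or 0 passing members each. Called higher with 1 passing member were phase II conjugation (sult1st5, ENSDARG00000003475, log2 1.09, SE 0.19), p53 and DNA damage (pcna) and erythroid markers (the globin gene hbae3, ENSDARG00000079305, log2 1.17, SE 0.22). Adjusted over the list alone they had 2 higher and 1 lower, 4 and 3, and 3 and 1. The sult1st5 gene, named after its values were seen, missed the threshold without any vehicle library or 1 mM replicate 2 (adjusted p 0.0624 to 0.128), and hbae3 without each vehicle library (0.0666 to 0.149). Their list adjusted p was 0.0393, 0.0393 and 0.0235, and adjusted p = 0.791, 0.69 and 0.842 with an estimated correlation. These calls were lost for phase II without vehicle replicate 3 (0.163) and 1 mM replicate 3 (0.524), for p53 without vehicle replicate 1 (0.0722) and 1 mM replicate 3 (0.28), and for erythroid markers without vehicle replicate 1 (0.278) and 1 mM replicate 3 (0.393), where 2 erythroid genes passed. Their medians were 0.22, 0.29 and 0.19. Called higher with 0 passing members were cholesterol synthesis (3 adjusted over the list alone, 0.0235), fatty acid oxidation (1 adjusted over the list alone, 0.0235), the respiratory chain (0 adjusted over the list alone, 0.0235), the proteasome (0 adjusted over the list alone, 0.000691) and macrophage markers (0 adjusted over the list alone, 0.0393). With an estimated correlation these had adjusted p = 0.44, 0.789, 0.889, 0.842 and 0.717. Called lower with 0 passing members were ribosome biogenesis (0 adjusted over the list alone, median -0.08, 0.0393) and endocrine pancreas markers (0 adjusted over the list alone, median -1.85, 0.000378), where ins (ENSDARG00000035350) stood at 16.4 ± 12.9 CPM in vehicle and 2.23 ± 3.82 CPM at 1 mM. These had adjusted p = 0.842 and 0.717 with an estimated correlation. Cholesterol synthesis was lost without vehicle replicate 3 (0.0588) and 1 mM replicate 3 (0.0593), fatty acid oxidation without vehicle replicate 3 (0.191), the respiratory chain without vehicle replicate 3 (0.0608), the proteasome without 1 mM replicate 3 (0.638), and ribosome biogenesis without vehicle replicate 1 (0.262), 1 mM replicate 1 (0.439) and 1 mM replicate 2 (0.067). Macrophage markers were lost without vehicle replicate 1 (0.325), each of 1 mM replicates 1, 2 and 3 (0.0771, 0.0888 and 0.201), 10 mM replicate 1 (0.0754) and 10 mM replicate 3 (0.099). Without 1 mM replicate 3 the respiratory chain was called in the other direction (0.00629). Over 14 alternatives each, the lowest adjusted p lay between 4.48e-09 and 0.0325. With only the 2 groups compared, dgat1a, sult1st5 and hbae3 missed the threshold (0.0742, 0.0536 and 0.0662).

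In all, 149 genes were higher and 16 lower at 1 mM than in vehicle by the edgeR quasi-likelihood test, and 117 and 6 of them changed at least 2-fold. The groups did not overlap in 17.7% of genes, where chance gives 10%. The number higher was 19, 19 and 47 without vehicle replicates 1, 2 and 3, 53 without 1 mM replicate 2, 85 with at least 5 CPM in 3 libraries and 92 with only the 2 groups compared. The number lower was 3, 2 and 4 without those vehicle replicates and 25, 1 and 29 without 1 mM replicates 1, 2 and 3. With no count filter the numbers were 418 and 69, and in DESeq2 392 and 78. Of 49 lists camera called 13, 8 without 1 mM replicate 3 and 1 with an estimated correlation, and fry called 2, both among the 13.

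**Figure D2:**
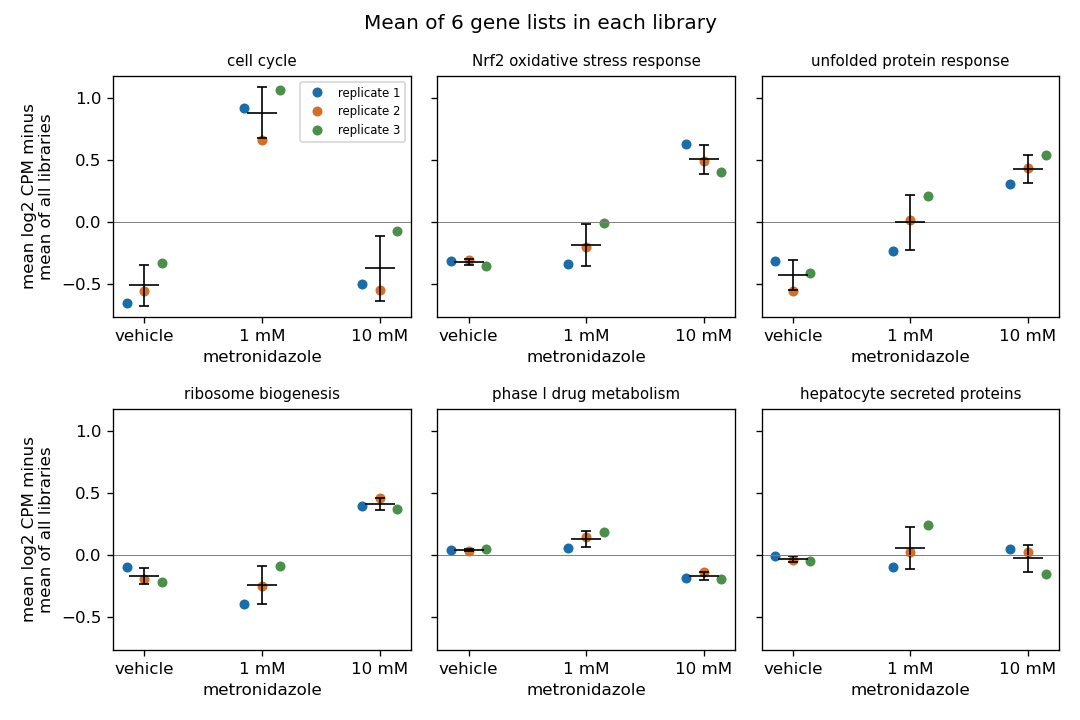
Mean log2 CPM of 6 gene lists in each library, less the mean of all libraries (y axis, log2), for the vehicle, 1 mM and 10 mM groups (x axis), with points for libraries and bars for mean ± SD of 3. The cell cycle list stands highest at 1 mM, where its median change from vehicle was 1.47, against 0.17 at 10 mM.

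Between the doses, 10 mM against 1 mM, 32 of 58 cell cycle genes were lower and 0 higher at 10 mM (42 and 0 adjusted over the list alone, median -1.28, camera adjusted p = 9.51e-21, and adjusted p = 0.166 with an estimated correlation), with cdk1 at log2 -1.47 (SE 0.33, adjusted p = 0.00835), ncapg at -1.17 (SE 0.22) and pcna, named after its values were seen, at -1.32 (SE 0.19). The replication origin gene orc6 (ENSDARG00000075682) was 2.72 ± 1.43 CPM at 1 mM and 0.209 ± 0.122 CPM at 10 mM (SD, n = 3 each, log2 -3.67, SE 0.52, adjusted p = 0.000499), and the checkpoint kinase gene chek1 (ENSDARG00000104765) 2.37 ± 1.07 and 0.285 ± 0.097 CPM (log2 -3.06, SE 0.49, adjusted p = 0.0011). Other genes far lower at 10 mM were kbtbd12 (ENSDARG00000001882, log2 -3.24, SE 0.42), or42a4 (ENSDARG00000105708, log2 -2.89, SE 0.40), cxcr4a (log2 -2.82, SE 0.54), cdca7a (ENSDARG00000077620, log2 -2.80, SE 0.34), rasl11b (log2 -2.71, SE 0.40) and gnai2b (log2 -2.71, SE 0.13, adjusted p = 5.81e-07). Genes far higher at 10 mM were nek2 (log2 4.60, SE 0.63), fosab (log2 4.54, SE 0.81), slc22a6l (log2 4.38, SE 0.75), the kinase gene sik1 (ENSDARG00000058606, log2 4.36, SE 0.65), pck1 (log2 4.25, SE 0.52), ptges3l (ENSDARG00000079462, log2 4.23, SE 0.33, adjusted p = 1.58e-05), chchd3b (ENSDARG00000034933, log2 4.04, SE 0.38) and btg2 (log2 3.96, SE 0.66). The adjusted p of these 16 genes was at most 0.00322 (cxcr4a). None overlapped between the groups, and each kept its call under every alternative that gave a value.

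Between the doses camera called 12 of 49 lists, 0 with an estimated correlation, and fry 13, of which 11 were the same. Ribosome biogenesis had 33 higher and 0 lower of 55 genes (38 and 0 adjusted over the list alone, median 0.65, adjusted p = 5.66e-18, and adjusted p = 0.166 with an estimated correlation). The Nrf2 response had 13 higher and 1 lower of 24 (15 and 1 adjusted over the list alone, median 0.59, adjusted p = 7.97e-13, and adjusted p = 0.166 with an estimated correlation). For the amino acid response these numbers were 14 and 0 of 30 (18 and 2 adjusted over the list alone, median 0.47, adjusted p = 3.68e-07, and adjusted p = 0.166 with an estimated correlation). For the glucocorticoid response they were 11 and 2 of 22 (13 and 2 adjusted over the list alone, median 0.72, adjusted p = 3.13e-06, and adjusted p = 0.349 with an estimated correlation). Gluconeogenesis and glycogen had 12 higher and 1 lower of 26 (13 and 2 adjusted over the list alone, median 0.32, adjusted p = 0.000226, and adjusted p = 0.28 with an estimated correlation). The unfolded protein response had 11 and 1 of 34 (12 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.00094, and adjusted p = 0.539 with an estimated correlation). Of 36 proteasome genes 8 were higher and 0 lower (10 and 0 adjusted over the list alone, median 0.24, adjusted p = 0.00402, and adjusted p = 0.851 with an estimated correlation), and of 26 heat shock genes 6 and 2 (7 and 3 adjusted over the list alone, median 0.30, adjusted p = 0.00966, and adjusted p = 0.352 with an estimated correlation). Bile acid synthesis and transport had 0 higher and 7 lower of 19 (1 and 7 adjusted over the list alone, median -0.16, adjusted p = 0.00402, and adjusted p = 0.28 with an estimated correlation). Phase I drug metabolism had 1 higher and 10 lower of 45 (2 and 12 adjusted over the list alone, median -0.26, adjusted p = 0.00573, and adjusted p = 0.352 with an estimated correlation). The interferon response had 1 higher and 6 lower of 25 (1 and 7 adjusted over the list alone, median -0.57, adjusted p = 0.0202, and adjusted p = 0.349 with an estimated correlation), with irf9 at log2 -0.95 (SE 0.14) and stat2 at -0.57 (SE 0.11). Against their lists, irf7 (log2 1.39, SE 0.22), cyp2y3 (ENSDARG00000101423, log2 0.41, SE 0.12) and hspb1 (ENSDARG00000041065, log2 -0.85, SE 0.23) moved the other way, with hmox1a (log2 -1.85, SE 0.28), creb3l3a (log2 -0.93, SE 0.26), ppp1r3ca (log2 -1.17, SE 0.18), per1a (log2 -0.55, SE 0.14), nr3c1 (log2 -0.50, SE 0.13) and fkbp4 (log2 -0.42, SE 0.13). All but irf7 were chosen after their values were seen. cyp2y3 missed the threshold without any vehicle or 10 mM library or 1 mM replicate 2 (adjusted p 0.051 to 0.118). hspb1 missed it without 1 mM replicate 3 or 10 mM replicate 2 or 3 (0.0519 to 0.0697). creb3l3a missed it without 1 mM replicate 1 or 2 or any 10 mM library (0.05 to 0.106). per1a missed it without 1 mM replicate 2 or 10 mM replicate 2 or 3 (0.052 to 0.0864). nr3c1 missed it without 1 mM replicate 1 or 2 or 10 mM replicate 1 or 3 (0.0549 to 0.0895). fkbp4 missed it without any vehicle library, 1 mM replicate 2 or 3 or 10 mM replicate 1 or 3 (0.0533 to 0.156). With only the 2 groups compared, cyp2y3, hspb1, creb3l3a, per1a, nr3c1 and fkbp4 missed it too (0.0505 to 0.0931), and with no count filter cyp2y3 and fkbp4 (0.0683 and 0.0599). The proteasome call was lost without 1 mM replicate 1 (0.146), and the interferon call without 1 mM replicate 3 (0.0981) and 10 mM replicate 3 (0.0508). Without 10 mM replicate 3, 6 genes of the unfolded protein response, 9 of the amino acid response and 6 of the glucocorticoid response passed, and without 1 mM replicate 3, 20 proteasome genes. The lowest of 14 alternatives of the 12 calls lay between 3.78e-26 for cell cycle and 0.00629 for interferon.

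In all, 1575 genes were higher and 1578 lower at 10 mM than at 1 mM by the edgeR quasi-likelihood test, and 622 and 743 of them changed at least 2-fold. The groups did not overlap in 33.7% of genes, where chance gives 10%, and without 10 mM replicate 1 the numbers were 1014 and 949. Over the 3 groups together, 3286 genes differed in the F test, and 2093 without 10 mM replicate 1.

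Of the genes called at both doses against vehicle, 45 were higher at both, c7b, cdk1, acta1a and rorcb among them, 7 were lower at both, gck, bhlhe41 and mtus1b among them, and 2 moved in opposite directions, the carotenoid oxygenase gene bco1 (ENSDARG00000104256, log2 0.73 at 1 mM and -0.52 at 10 mM) and si:ch73-335l21.1 (ENSDARG00000036414, log2 -0.65 and 0.40). Both were chosen after their values were seen. At 1 mM bco1 missed the threshold without any vehicle library, 1 mM replicate 2 or 10 mM replicate 2 (adjusted p 0.0504 to 0.195). At 1 mM si:ch73-335l21.1 missed it without any vehicle library, 1 mM replicate 1 or 2 or 10 mM replicate 1 (0.054 to 0.18). At 10 mM bco1 missed it without vehicle replicate 1 or 3 or 10 mM replicate 2 or 3 (0.0525 to 0.122). At 10 mM si:ch73-335l21.1 missed it without any vehicle or 10 mM library or 1 mM replicate 2 (0.0532 to 0.166). With only the 2 groups compared both missed it at 1 mM (0.0636 each), and with no count filter si:ch73-335l21.1 at 10 mM (0.0643). Independent calls would give 14.5, 1.19 and 12.6. Simulated unchanged groups gave at most 1, but few genes pass there, so this decides nothing. Across the 16766 genes, which are not independent replicates, the log2 changes at both doses had a Pearson r of 0.350 and a Spearman rho of 0.311. The simulations gave 0.496 and 0.457, so these r values do not show a shared response. The covariance was 0.147 against 0.0865 simulated. Over the 2878 genes called at 10 mM it was 0.368 against 0.0429, and r 0.518 against 0.490 (simulated up to 0.571). The simulations had no such selection, so these values decide nothing. Without vehicle replicates 1, 2 and 3, r over all genes was 0.459, 0.445 and 0.462.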

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

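Apart from the counts over other splits of the libraries, every test of an explanation in this part was chosen after the result had been seen. Camera picked 12 gene lists at 10 mM against 1 mM (adjusted p 9.51e-21 to 0.0202). That alone does not show a group difference, as other splits called up to 16. With an estimated correlation none of these calls held (adjusted p from 0.166 to 0.851), and fry called 11 of the 12, not the proteasome (adjusted p = 0.189). The median log2 difference was 0.65 for ribosome biogenesis, 0.59 for the Nrf2 response and 0.47 for the amino acid response. For the glucocorticoid response it was 0.72 and for gluconeogenesis and glycogen 0.32. The unfolded protein response stood 0.40, heat shock 0.30 and the proteasome 0.24 higher. The bile acid list stood at -0.16, interferon at -0.575, phase I at -0.26 and cell cycle at -1.28.

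Cell cycle genes, with a median log2 change of 1.47 at 1 mM, were weighed against 1 odd library and against cells of other types. Without 1 mM replicate 3, the library apart from the others, the median was 1.41 (adjusted p = 8.67e-58), so that library was not the whole cause. The 4 marker lists as scarce in vehicle as cell cycle transcripts had medians of at most 0.30, for neural and eye markers (SE over members 0.31), and endocrine pancreas was called lower (adjusted p = 0.000378, and adjusted p = 0.717 with an estimated correlation), but these markers lie near the floor, at 0.483 to 0.869 CPM, and exclude nothing. The 12 lists of more abundant markers had medians of at most 0.25, for kidney tubule (SE 0.16), and of them macrophage and erythroid markers were called higher (adjusted p = 0.0393 and 0.0235, and adjusted p = 0.717 and 0.842 with an estimated correlation), which leaves other cells open too, since a small share of them could leave abundant markers nearly unmoved. A biological effect of the lower dose and a difference in stage or clutch between the groups stay open, since the labels give neither stage nor clutch per library.

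The distance of 1 mM replicate 3 from the other libraries was weighed against transcript length and library size. Its genes with long transcripts had a median log2 deviation of -0.55, against -0.06 to 0.24 in the other libraries, the direction a lower RNA quality would give. The mean of its 76 ribosomal protein genes, which are short, was 0.72, against at most 0.20 in the others, as the same explanation would give. It stays open, since only 16 of 46 long genes passed the count filter (34.8%), and ribosomal protein genes alone do not part length from a change of these genes. Its total of 36 M counts lay inside the range of the others, which excludes library size, and no biological explanation was tested.

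Phase I genes at 10 mM, of which 16 fell, were weighed against a smaller share of hepatocytes and against reads shared between near-identical gene copies. Their mean log2 change lay below that of hepatocyte secreted proteins (difference -0.22, SE 0.06), so fewer hepatocytes were not the whole cause. Of 33 genes with cyp2k, cyp2aa, cyp2ad, cyp2n, cyp2p, cyp2v, cyp2x, cyp2y, cyp3a or cyp3c symbols 14 fell, and of the 12 others 2 (Fisher p = 0.164), too few to decide on shared reads, which stay open. Reads moved between listed copies would leave the sum of a family unchanged, and the sums of cyp2aa, cyp2ad, cyp2p and cyp2x were lower in each 10 mM library than in each vehicle library (at most 0.845 of the vehicle mean), which excludes such moves as the whole cause there. The sums of cyp2k and cyp3c overlapped (at least 0.891), as such moves would give, and a response to the drug stays open.

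The libraries of each pair of groups can be split in 10 ways, too few for a share under 0.05. The real groups gave 2878, 165 and 3153 genes at 10 mM, at 1 mM and between the doses, each the highest of 10, with at most 1 gene in any other split, at 1 mM. They gave 14, 13 and 12 lists in camera, and other splits up to 16, 19 and 16. Counting the real one, 2, 4 and 4 of the 10 splits reached that number, which does not set the real groups apart. Of 100 splits into 3 groups drawn from 280, only the real groups reached 3286 genes. The 6 others keeping the 10 mM libraries together gave 2011 to 2467, and the 93 parting them at most 19. So the 3286 rest mostly on 10 mM.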

How the results depend on the processing

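Of 409 results of named genes past the threshold, 284 kept their direction and their side of it under every alternative that gave a value. None changed direction. The others lost the call under at least 1. Over all alternatives, these results kept the call 6248 times and lost it 646 times, and results of named genes not past the threshold stayed so 5033 times, gained a call 148 times and changed sign 150 times. The calls of lists were kept 465 times, lost 80 times and reversed once, and 52 of 64 counts of passing members stayed within 1.5 times. The halved counts and these member counts were chosen after the data were seen. A left-out library leaves at least 2 per group, so part of each loss is that of having fewer samples, and the cause was not otherwise tested for any change given here. Depth limits genes of few counts: the filter at 5 CPM left no value for genes such as cdk1, gck, nek2 and orc6. Of simulated 2-fold changes, 39 to 49% were recovered.

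Under another filter, in another tool or with only the 2 groups compared, the numbers of genes moved by over 1.5 times at 1 mM alone. From 149 higher and 16 lower genes, the numbers went to 418 and 69 with no count filter and 392 and 78 in DESeq2. The 149 went to 85 with at least 5 CPM in 3 libraries and 92 with only the 2 groups compared. A log2 change of at least 1 left 742 of 1633 higher and 477 of 1245 lower genes at 10 mM, 6 of 16 lower genes at 1 mM, and 622 of 1575 higher and 743 of 1578 lower genes between the doses. Called lists fell from 14, 13 and 12 to 0, 1 and 0 with an estimated correlation, and to 2 at 1 mM with fry.

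Leaving out 1 library at a time, the genes higher and lower at 10 mM ran from 1084 to 2282 and from 770 to 1784. At 1 mM the higher ran from 19 to 177 and the lower from 1 to 29. Between the doses they ran from 1014 to 2067 and from 949 to 1835, and the genes differing among the 3 groups from 2093 to 4486. Called lists at 1 mM ran from 8 to 19, and the correlation of the changes at both doses from 0.311 to 0.462. The list of the respiratory chain at 1 mM had an adjusted p of 4.48e-09 to 0.0608, and its test changed direction without 1 mM replicate 3 (adjusted p = 0.00629).

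With the replicate number as a block, 1417 and 1038 genes were called at 10 mM, 1320 and 1306 between the doses, and 8 lower genes at 1 mM, and the numbers of lists did not move. No other number moved by over 1.5 times. Deviations of same-numbered libraries correlated at -0.111 to 0.0565 and those of others at -0.0429 to 0.125, and 1 of 9 libraries correlated best with its own number, so the numbers were not taken as pairs. Lost under the block were the calls of gc, cyp1c1, ctsl.1, erg, arxa, krt5, slc20a1a, cyp1c2, cyp2k6, cyp2k8, gpia, haao, aldh2.1, bcl2l1, pdgfrb, cxcl12b, grna and si:ch73-335l21.1 (0.0531 to 0.142) at 10 mM, of gck, neil3, oat, dgat1a, bco1 and si:ch73-335l21.1 (0.061 to 0.0804) at 1 mM and of fkbp4 and cyp2y3 (0.0728 to 0.0747) between the doses, with adjusted p in brackets. Under the block these log2 changes, not called, changed sign: ercc6l at 10 mM (-0.16), cox8a (ENSDARG00000095273, -0.012), col2a1b (ENSDARG00000011407, 0.032) and acss2 (-0.0061) at 1 mM, and rpl21 (ENSDARG00000010516, 0.014), rpl9 (ENSDARG00000037350, -0.0047) and sparc (0.0044) between the doses.

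Between the doses sparc stood at 0.012 with DESeq2 size factors, 0.0058 with no count filter and 0.011 in DESeq2, the cause not tested. With at least 5 CPM in 3 libraries, slc30a1a stood at 0.0050 and col1a1b at 0.0048 at 1 mM. With halved counts ercc6l stood at -0.024 at 10 mM and nek2 at 0.12 at 1 mM. The halved counts moved no number of genes or lists by over 1.5 times.

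Leaving out 1 library at a time also changed the sign of log2 changes that were not called, with lowest and highest values in brackets. At 10 mM these were ercc6l (-0.77 to 0.43), selenoo1 (-0.10 to 0.12), zgc:92590 (ENSDARG00000040282, -1.17 to 0.35), col2a1b (-0.90 to 1.98) and dgat1a (-0.34 to 0.062). At 1 mM they were fosab (-0.093 to 1.02), nek2 (-0.47 to 0.44), pck1 (-0.22 to 0.70), cxcr4a (-0.26 to 0.74), slc2a5 (-0.21 to 0.15), bco2l (-0.13 to 0.079), sik1 (-0.66 to 0.52), gc (-0.13 to 0.0059), nqo1 (-0.018 to 0.15), cebpb (-0.10 to 0.093), irf7 (-0.29 to 0.11), stat2 (-0.074 to 0.034), hsd3b7 (-0.037 to 0.066), slc25a1b (ENSDARG00000076381, -0.18 to 0.045), apoa4a (-0.13 to 0.36), abca1a (ENSDARG00000074635, -0.26 to 0.070), agxtb (ENSDARG00000018478, -0.15 to 0.052), akr1b1.1 (-0.12 to 0.17), akr1a1a (-0.17 to 0.20), mt-nd4l (ENSDARG00000063916, -0.15 to 0.13), cox8a (-0.28 to 0.22), rpl9 (-0.040 to 2.32), nop58 (-0.045 to 0.13), sgk1 (-0.14 to 0.37), slc30a1a (-0.11 to 0.049), vtg7 (-0.078 to 0.82), ulk1a (-0.0045 to 0.10), mcl1b (-0.12 to 0.51), baxa (-0.15 to 0.24), cdh1 (ENSDARG00000102750, -0.16 to 0.044), hnf1ba (ENSDARG00000006615, -0.27 to 0.0068), dll4 (-0.10 to 0.024), col1a1b (-0.11 to 0.058), pnp5a (-0.0017 to 0.32), abcb9 (-0.39 to 0.0061), coro1a (ENSDARG00000054610, -0.067 to 0.23), cxcr4b (ENSDARG00000041959, -0.067 to 0.38), nprl3 (-0.061 to 0.022), gp1bb (ENSDARG00000074441, -0.48 to 0.22), zgc:92590 (-1.38 to 0.22), tpm2 (-0.071 to 0.031), col11a1a (ENSDARG00000026165, -0.86 to 0.64), col2a1b (-0.40 to 0.11), egr1 (ENSDARG00000037421, -0.092 to 0.90), taldo1 (ENSDARG00000103369, -0.13 to 0.043), creb3l3a (-0.33 to 0.36), mlxipl (-0.36 to 0.10), acss2 (-0.051 to 0.10), relb (-0.29 to 0.060), eci1 (-0.095 to 0.25), gpia (-0.092 to 0.11), haao (-0.035 to 0.091), glud1a (-0.018 to 0.10), slc39a10 (-0.26 to 0.10), pdgfrb (-0.033 to 0.47) and cd68 (-0.14 to 0.0067). Between the doses they were cyp1c1 (-0.0065 to 0.19), rpl21 (-0.21 to 0.29), rpl9 (-0.47 to 1.28), lect2.1 (-0.21 to 0.58), creg1 (-0.21 to 0.10), zfpm1 (ENSDARG00000041572, -0.17 to 0.047), itga2b (ENSDARG00000018687, -0.093 to 0.27), zgc:92590 (-0.14 to 0.66), ptf1a (ENSDARG00000014479, -0.85 to 0.28), krt5 (-1.78 to 1.89), krt92 (ENSDARG00000036834, -0.16 to 0.10), col2a1b (-0.69 to 2.19), sult1st5 (-0.19 to 0.17), cyp1c2 (-0.092 to 0.20), cyp2k6 (-0.29 to 0.45), sparc (-0.13 to 0.12) and grna (-0.0070 to 0.10).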

Other observations

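Outside the lists, the monocarboxylate carrier gene slc16a6b (ENSDARG00000060246), chosen after its values were seen, rose at 10 mM from 1.82 ± 0.25 to 25.6 ± 8.81 CPM (SD, n = 3 each, log2 3.81, SE 0.28, adjusted p = 8.28e-06). It stood at 2.76 ± 0.669 CPM at 1 mM, which was not called (adjusted p = 0.446). The call at 10 mM held under every alternative tried.

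The hypothesis of a fasting-like state at 10 mM was tested, after the values of gck and pck1 had been seen. Such a state would lower gck and raise pck1, as found, and lower genes of fatty acid and triglyceride synthesis. That list had a median log2 change of 0.38, with 8 higher (1 also named ccdc57) and 2 lower of 24. Its adjusted p was 0.0174, 0.482 with an estimated correlation and 0.0717 without vehicle replicate 3. This argues against such a state but leaves it open, since the call was lost and mlxipl and acss2 were lower. Higher foxo1a and igfbp1b go with it, as do PPARGC1A, cpt1b and cpt1ab of fatty acid oxidation. That list was not called (7 higher, 3 lower of 38, adjusted p = 0.246).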
